A study of Arabidopsis thaliana with 10 samples.

How the data were processed

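Rosette leaves of Columbia wild type and of the lines flu, ex1/ex2/flu, ex1/flu and ex2/flu were profiled on ATH1 arrays, with 2 biological replicates per genotype of 5 pooled mature plants each. Plants grew on soil in continuous light of 100 µmol m-2 s-1 until bolting began, spent 8 h in the dark and were harvested after 30 min of light. The EX1 and EX2 lines carried T-DNA insertions, and the flu line descended from a Landsberg erecta mutant after 5 backcrosses to Columbia. Biotin-labelled cRNA was made from total RNA.

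The deposited table held the signal of each probe set as a linear intensity, from the authors' processing with GCOS 1.2 and MAS5 as named in the submitters' processing notes. The mean of each array between its 2nd and 98th percentile lay between 499.796 and 499.816, so every array had been scaled to a common level. The scaling target and background settings are not given in the sources used here. The table had no detection calls, so dim probe sets were set aside by level. The ratio of the 3' to the 5' control probe set was 2.45 to 3.09 for actin, 0.836 to 1.17 for GAPDH and 1.04 to 1.49 for ubiquitin over the 10 arrays.

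The 64 control probe sets were left out, and of the remaining 22746 those that reached the 40th percentile of their array on at least 2 of the 10 arrays were kept (14435, 63.5%). Signals were log2-transformed without an offset and without further normalization. In R 4.3.3, limma 3.58.1 (lmFit, contrasts.fit, and eBayes with an intensity trend) was fitted to all 10 arrays with 1 mean per genotype, which left 5 residual degrees of freedom and a prior of 10.0. Errors of log2 differences are limma's moderated standard errors. For a genotype below the 40th percentile on both arrays, a bound was given, the mean log2 signal of the other genotype minus the mean log2 of that percentile, with limma's adjusted p from the measured values. This rule was added after the data were seen. Probe sets with a Benjamini-Hochberg adjusted p under 0.05 over the 14435 were called, and were also counted at a difference of at least 2-fold. The arrays' number limits the precision. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.

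The comparisons were flu against wild type, each EXECUTER line against flu and against wild type, ex1/ex2/flu against ex1/flu, and the interaction of ex1 and ex2 within the flu background. These, the gene lists, the rule for naming genes and most alternatives were chosen before the data were examined. The comparison of ex1/flu with ex2/flu was added afterwards.

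Probe sets were assigned to genes with the given table of the array, which names no genome build. It paired 13513 probe sets with 1 gene, 503 with several, and did not list 8730. Of the kept probe sets 7815 had 1 gene, and 7786 of these matched a locus (7717 loci) in the RefSeq table of assembly TAIR10.1, which was used for names and neighbourhood only. The genes named were EX1, the 14 highest and 8 lowest in flu against wild type, the 5 highest and 5 lowest in each other comparison (3 and 3 for the interaction), and up to 4 called members of each list, or 2 members where none was called. Genes picked as highest or lowest had to be assigned to 1 gene, be called, have both arrays of one genotype beyond both of the other, and reach the median signal of kept probe sets (409) in the higher genotype. For the interaction the separation of arrays was not required. List members had to be assigned to 1 gene but needed neither the separation nor the signal level. Further genes (WRKY6, AT3G28580, the members of gene families and the genes shared by several lines) were named after their values were seen, and so were the differences of already named genes in other comparisons.

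Of 328 loci in 19 fixed lists, 47 had a probe set of their own in the annotation and 45 were kept. The 7 lists with at least 3 measured members were tested: singlet oxygen reporters (3 of 14), scavenging of superoxide and hydrogen peroxide (6 of 22), stress WRKY factors (3 of 17), photosynthesis (9 of 44), tetrapyrrole synthesis (9 of 30), abscisic acid, cold and drought (3 of 18) and cytosolic ribosomal proteins (3 of 13). Members of the jasmonate (1), salicylate (1), zinc-finger (2), calcium and kinase (2), detoxification (2) and clock (2) lists were read singly. The ethylene, heat shock, tryptophan and indole, senescence, inflorescence and root lists had 0 measured members, so the check for other tissues was void. Lists were tested with camera (preset correlation 0.01, and again with the correlation estimated), adjusted over the lists of a comparison, and with fry, whose p was not adjusted. Since the lists were thinly covered, 34 groups (families of at least 5 loci sharing a symbol prefix, and the plastid-encoded probe sets) were added before any difference was seen.

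The share of the flu response left in a line was the ratio of median differences from wild type, line over flu, for probe sets that changed at least 2-fold in flu on the arrays of a replicate number, measured on the arrays of the other number, and averaged over both ways. Calls around FLU were counted within 2 Mb, and within 1 and 4 Mb, with Fisher's exact test, adjusted over 24 tests. Replicate numbers did not pair the arrays in general: deviations from the genotype mean correlated above 0.1 in 1 of 10 pairs of genotypes (-0.0862 to 0.431). That pair was ex1/flu with ex2/flu (0.431), so the comparison of these lines left a shared deviation out of the model. No block was planned for the main fit, and the replicate number as a block was an alternative. The alternatives tried were quantile normalization, median centring, an offset of 22.4 (the 20th percentile of the table), no filter, a filter at the 50th percentile, no intensity trend, a fit of only the arrays compared, an adjusted p under 0.01, the replicate number as a block, a 4-fold selection, and leaving out each array. A block for the level of the spike-in controls and leaving out probe sets within 4 Mb of FLU were added after the data were seen.

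The steps were tested on simulated data of 14435 probe sets, 5 runs each. For flu against wild type, 22.1% of 1.5-fold, 78.5% of 2-fold and 98.2% of 4-fold changes were recovered, and 43 of 71175 unchanged probe sets were called. For the interaction the shares were 6.87%, 43.3% and 92.7%, with 35 unchanged probe sets called. A response left of 50%, 100% and 0% was estimated as 49.5%, 99.8% and 0.293%. In each simulated line all changed probe sets kept the same share, and the arrays did not differ in spike-in level. These estimates therefore do not give the error of the shares in the real data. A shifted list was called in 5 of 5 runs for flu against wild type, with 1 of 30 unshifted lists, and a shifted window in 5 of 5, with the unshifted line in 0 of 5. The simulated probe sets varied independently of each other, so these counts do not give the rate of false list or window calls in the real data.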

Results

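RNA abundance was measured on 10 ATH1 arrays of rosette leaves of Arabidopsis thaliana, 2 arrays for each of 5 genotypes. These were wild type (Columbia), the flu mutant, flu lines lacking EXECUTER1 (ex1/flu) or EXECUTER2 (ex2/flu), and a flu line lacking both (ex1/ex2/flu). The flu mutant accumulates the chlorophyll precursor protochlorophyllide in the dark and releases singlet oxygen in its plastids when light returns. Mature plants were kept in the dark for 8 h and harvested after 30 min of light, and each array held the pooled material of 5 plants. The table gave a signal for 22746 probe sets of genes, of which 14435 were tested. The median signal of an array lay between 158 and 171, the highest between 28449 and 36240. Within a genotype the arrays correlated at 0.973 to 0.985 across probe sets, and the median standard deviation between replicates was 0.11 (ex1/ex2/flu) to 0.18 (ex1/flu) on the log2 scale. The number of arrays limits the precision: an exact permutation test of 2 arrays against 2 cannot give a two-sided p below 0.333, so tests were made with limma across all probe sets.

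The EX1 probe set (AT4G33630) checked the lines. Its mean log2 signal was 9.42 in wild type, 9.59 in flu and 9.22 in ex2/flu, and it was lower in ex1/flu (7.92) and ex1/ex2/flu (7.67). It fell by 1.67 ± 0.17 (SE, n = 2 per genotype) in ex1/flu against flu and by 1.92 ± 0.17 in ex1/ex2/flu against flu, with limma adjusted p of 0.000303 and 1.06e-05. In flu against wild type its difference was 0.17 (adjusted p 0.719), and in ex2/flu against flu it was -0.37 (adjusted p 0.351). FLU and EX2 were not analysed here, since no probe set of the annotation table used was assigned to them.

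Flu was compared with wild type to find the response that follows the release of singlet oxygen. Every array was of leaves taken after 30 min of light, so differences already present in the dark are part of what is called the flu response here. STZ (AT1G27730, also called ZAT10, a zinc-finger repressor of stress responses) rose 7.46-fold (log2 2.90 ± 0.15, n = 2 per genotype, limma adjusted p 1.25e-08), from a mean log2 signal of 9.70 in wild type to 12.60 in flu. Where a genotype lay below the level of the filter (the 40th percentile of the array) on both arrays, the difference is given as a lower bound, the distance of the other genotype from that level. In wild type this was so for AT5G66650, which rose by at least 3.54 log2 units (limma adjusted p 7.95e-08), AT2G22880, by at least 2.90 (6.57e-06), and DLAH (AT1G30370, a lipase of the DAD1-like family), by at least 2.64 (3.12e-06), so these have no rank. AT1G05575 (3.42 ± 0.23) and AT4G29780 (3.11 ± 0.18) also rose, AT1G76600 rose 8.01-fold, and AT1G72920 and AT1G72940, both of the TIR type found in immune receptors, rose by 2.91 ± 0.17 and 2.46 ± 0.18. AT3G10930 (2.85 ± 0.21), AR781 (AT2G26530, 2.61 ± 0.18), AT4G37290 (2.53 ± 0.22), AT2G32030 (2.53 ± 0.19) and AT1G35210 (2.38 ± 0.24) complete the group. Of these risers, AT3G10930 lies within 4 Mb of FLU. The 8 genes picked as falling most by the naming rule, limited to those whose signal reached the median of kept probe sets, were AT3G19515 (by at least 3.12, being below the level of the filter in flu), AT3G07950 (-1.71 ± 0.20), AT3G11500 (-1.68 ± 0.24), AT1G76960 (-1.34 ± 0.27), TBL26 (AT4G01080, -1.30 ± 0.25), AT3G14220 (-1.22 ± 0.15), AT1G31690 (-1.18 ± 0.26) and GIS (AT3G58070, -1.16 ± 0.19). Among these, AT3G19515, AT3G07950, AT3G11500 and AT3G14220 lie within 4 Mb of FLU, and AT1G76960 and AT1G31690 were not called without the intensity trend. In all, 408 probe sets were higher and 147 lower in flu at a limma adjusted p under 0.05, 256 and 55 of them by at least 2-fold. Without 1 array the total of 555 fell to 265 (wild type 1), 295 (wild type 2), 328 (flu 1) or 256 (flu 2).

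**Figure D1:**
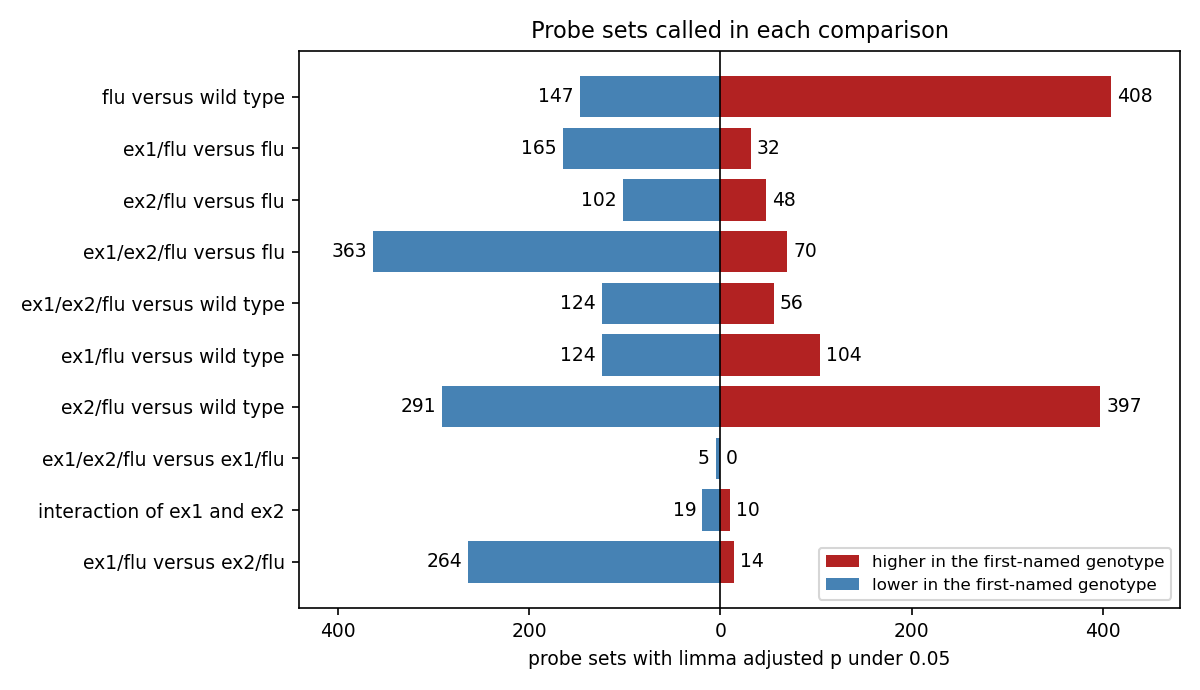
Probe sets called higher (red) or lower (blue) at a limma adjusted p under 0.05 in each comparison, as counts of the 14435 tested, with 2 arrays per genotype. Calls were mostly higher in flu against wild type (408 of 555) and mostly lower in ex1/ex2/flu against flu (363 of 433).

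Of the gene groups fixed before the data were examined, 2 of 3 measured WRKY factors of stress and defence and 2 of 3 measured singlet oxygen reporters were called higher in flu. Neither group was called as a whole by camera when the correlation of its members was estimated (camera adjusted p 0.0623 for both). By fry, which does not set the members against other genes, the unadjusted p was 0.000661 (WRKY factors) and 0.000208 (reporters). WRKY53 (AT4G23810) rose by 1.70 ± 0.19 log2 units (n = 2 per genotype, limma adjusted p 3.5e-05) and WRKY22 (AT4G01250) by 1.00 ± 0.23 (0.0221), and WRKY6 (AT1G62300) was not called (0.075). The calmodulin-like genes CML37 (AT5G42380) and CML38 (AT1G76650), which answer calcium signals and touch, rose by 1.84 ± 0.29 and 1.19 ± 0.31. Of the reporters, STZ and AT5G64870 (1.18 ± 0.28) were called and AT3G28580 was not (0.82 ± 0.35). LHCB4.2 (AT3G08940), an antenna protein of photosystem II whose locus lies within 4 Mb of FLU, fell by 1.02 ± 0.12, and PORB (AT4G27440), which reduces protochlorophyllide in light, fell by 0.58 ± 0.12. CML38 was no longer called without the filter on dim probe sets or without the intensity trend, AT5G64870 lost its call in the same settings, WRKY22 without the filter and PORB without the trend. Over the 7 lists with at least 3 measured members, camera called the reporters (2 of 3 measured members higher, 3 adjusted over the list alone, adjusted p 4.61e-06) and the WRKY factors (2 of 3, 3 adjusted over the list alone, adjusted p 1.17e-05). With the estimated correlation the adjusted p of 0.0623 ended both calls. The reporters were chosen in earlier flu experiments, so their count is not independent evidence. No member of the scavenging list was called by limma (0 of 6, 0 adjusted over the list alone, camera adjusted p 0.999).

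Other list members that were not called had small or variable differences in flu. COR15B (AT2G42530) and COR15A (AT2G42540), a pair of cold-regulated genes, stood at -0.59 ± 0.19 (limma adjusted p 0.121, n = 2 per genotype) and -0.38 ± 0.18 (0.348). UGT73B5 was at 0.96 ± 0.44, CHIL at 0.27 ± 0.36 and the jasmonate gene OPCL1 at 0.41 ± 0.18. GSTU25 lay below the level of the filter on the wild type and flu arrays and GI on the flu arrays, so no difference is given for them. The antioxidant enzymes GR and TAPX were at 0.19 ± 0.18 and -0.17 ± 0.14, SAG101 at -0.20 ± 0.24, and the ribosomal protein genes AT5G15200 and AT3G09630 at 0.13 ± 0.10 and 0.08 ± 0.13. The photosynthesis and tetrapyrrole lists each had 1 of 9 measured members lower (1 and 2 adjusted over the list alone), the cold and drought list 0 of 3 (1 lower adjusted over the list alone) and the ribosomal list 0 of 3. Median, mean and camera direction differed in sign for the scavenging and tetrapyrrole lists in this comparison.

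**Figure D2:**
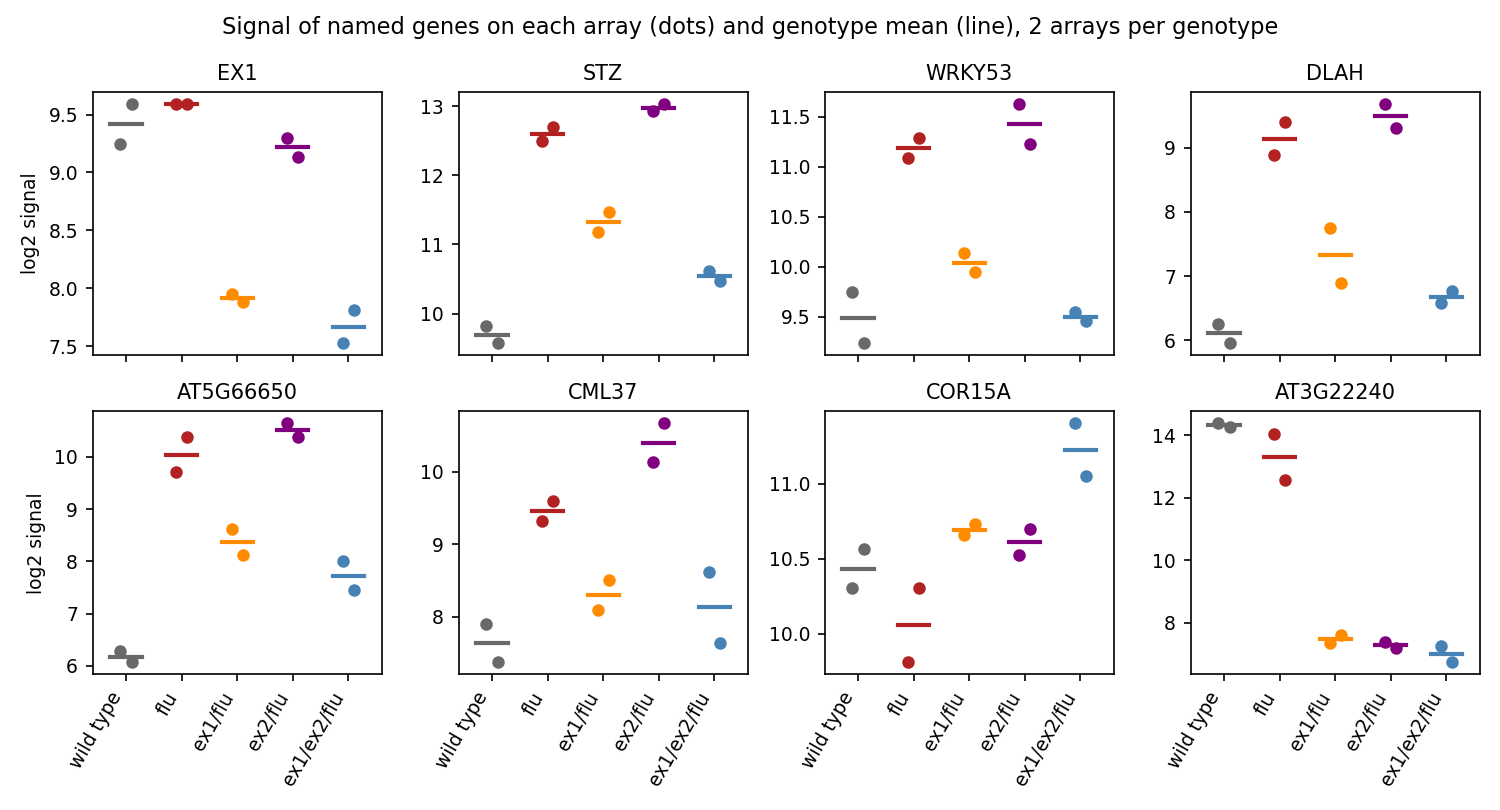
Log2 signal of 8 named genes on each array (dots) with the genotype mean (line), 2 arrays per genotype in 5 genotypes. STZ averaged 12.60 in flu, 11.33 in ex1/flu, 12.98 in ex2/flu and 10.55 in ex1/ex2/flu, against 9.70 in wild type.

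The effect of losing EX1 was read from ex1/flu against flu. DLAH fell by 1.82 ± 0.27 log2 units (n = 2 per genotype, limma adjusted p 0.00194), AT3G10930 by 2.07 ± 0.21, AT3G48650 by 1.76 ± 0.21, STZ by 1.27 ± 0.15 and WRKY53 by 1.15 ± 0.19. WRKY6 also fell (adjusted p 0.0299), and the reporter AT5G64870 fell by 1.55 ± 0.28. AT3G22240 fell by 5.81 ± 0.33, the most of the named genes, from a mean log2 signal of 13.30 to 7.49. The rises were smaller: CRR42 (AT5G20935) by 1.13 ± 0.17, AT5G03120 by 1.04 ± 0.19, the plastid ribosomal protein gene rpl20 by 0.99 ± 0.20, GIS by 0.90 ± 0.19 and AT5G54970 by 0.84 ± 0.17. All of these but CRR42 lost their call without the intensity trend. In all, 32 probe sets were higher and 165 lower, 8 and 94 of them by at least 2-fold. The total of 197 was 95 without flu 1 and 58 without flu 2, and in this last fit DLAH was not called. Of the lists, camera called the reporters (0 higher and 2 lower of 3, 2 adjusted over the list alone, adjusted p 1.66e-05), the WRKY factors (0 and 2 of 3, 3 adjusted over the list alone, 3.44e-05) and the cold and drought genes (upward, 0 of 3 called by limma, 1 higher adjusted over the list alone, adjusted p 0.00811). With the estimated correlation the adjusted p was 0.0751, 0.0751 and 0.238. Fry gave an unadjusted p of 0.00188, 0.00214 and 0.0408.

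What losing EX2 changes was read from ex2/flu against flu. The cell-wall enzyme genes XTH18 (AT4G30280) and XTH19 (AT4G30290) rose by 1.50 ± 0.28 and 1.26 ± 0.17 log2 units (n = 2 per genotype, limma adjusted p 0.0224 and 0.00371). AT3G11500 rose by 1.81 ± 0.24, AT4G33960 by 1.31 ± 0.19, AT3G07950 by 1.30 ± 0.20, LHCB4.2 by 1.04 ± 0.12 and COR15B by 1.00 ± 0.19. AT3G11500, AT3G07950 and LHCB4.2 lie within 4 Mb of FLU and had fallen in flu. AT3G22240 fell by 6.01 ± 0.33, CHI (AT2G43570, a chitinase gene) by 1.89 ± 0.22, AT3G18250 by 1.68 ± 0.31, AT1G68620 by 1.62 ± 0.28 and IVD (AT3G45300, an enzyme of leucine breakdown) by 1.40 ± 0.25. STZ stood at 0.39 ± 0.15 and WRKY53 at 0.24 ± 0.19, and neither was called. In all, 48 probe sets were higher and 102 lower, 22 and 59 of them by at least 2-fold. The total of 150 was 42 without the filter, 10 without the intensity trend, 73 without either wild type array, 8 without flu 1, 78 without flu 2, 37 without ex2/flu 1, 59 without ex2/flu 2, and 257 or 258 without ex1/flu 1 or ex1/flu 2. XTH18, AT3G18250, AT1G68620 and IVD were not called without the filter, and these and AT3G11500 and AT3G07950 not without the trend. Of the lists, camera called the cold and drought genes (1 of 3 higher, 2 adjusted over the list alone, adjusted p 0.00349, and 0.441 with the estimated correlation). Fry gave this list an unadjusted p of 0.0151.

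The loss of both genes was read from ex1/ex2/flu against flu. AT3G10930 fell by 2.80 ± 0.21 log2 units (n = 2 per genotype, limma adjusted p 2.06e-06), AT2G22880 by 2.65 ± 0.49, DLAH by 2.47 ± 0.27, AT5G66650 by 2.32 ± 0.25 and STZ by 2.05 ± 0.15. WRKY53 fell by 1.69 ± 0.19 to a mean log2 signal of 9.50, against 9.49 in wild type, WRKY22 fell by at least 1.04 (to below the level of the filter), and the reporters AT3G28580 and AT5G64870 by 1.61 ± 0.35 and 1.36 ± 0.28. AT3G22240 fell by 6.31 ± 0.33. COR15A rose by 1.17 ± 0.18, COR15B by 1.04 ± 0.19, PORB by 0.56 ± 0.12, TBL26 by 1.09 ± 0.25, GIS by 1.08 ± 0.19, AT5G41670 by 1.05 ± 0.19 and rpl20 by 1.04 ± 0.20. TBL26 was not called without the filter, and TBL26 and AT2G22880 not without the intensity trend. In all, 70 probe sets were higher and 363 lower, 14 and 216 of them by at least 2-fold. The total of 433 was 277 without the trend and 664 with only the arrays compared. It was 214 without flu 1, 195 without flu 2, 129 without ex1/ex2/flu 2, and 655 or 653 without ex1/flu 1 or ex1/flu 2. Of the lists, camera called the reporters (0 higher and 3 lower of 3, 3 adjusted over the list alone, adjusted p 3.23e-07), the WRKY factors (0 and 2 of 3, 3 adjusted over the list alone, 3.16e-06), the cold and drought genes (2 of 3 higher, 2 adjusted over the list alone, 0.00237) and tetrapyrrole synthesis (1 of 9 higher, 1 adjusted over the list alone, 0.0314). With the estimated correlation the adjusted p was 0.0507, 0.0507, 0.174 and 0.288. Fry gave an unadjusted p of 0.000297, 0.000405, 0.00769 and 0.0703.

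How much of the flu response was left in each line was measured on arrays other than those that selected the probe sets. For probe sets at least 2-fold higher in flu (374 and 370 in the 2 selections), ex1/flu kept 42.6% ± 8.65 (SD, n = 2 selections) of the response, ex2/flu 96.5% ± 22.9 and ex1/ex2/flu 26.8% ± 7.42. The 2 selections swap the same arrays, and all lines share the wild type and flu arrays, so this SD is not a spread between independent replicates. Wild type and flu also lay in different groups of spike-in level (described below): low and high for replicate number 1, high and low for number 2. For probe sets lower in flu (205 and 166) the shares were 75.1% ± 16.5, 73.0% ± 22.9 and 56.5% ± 43.2, a spread too wide to rank the lines. STZ, WRKY53, DLAH and AT5G66650 each had a lower mean in ex1/flu than in flu and the lowest of the flu lines in ex1/ex2/flu, while their means in ex2/flu lay above those in flu. Without the filter the share of the higher response was 72.3% in ex1/flu, -11.2% in ex2/flu and 121% in ex1/ex2/flu, since the selection then held 1719 and 2117 probe sets whose median difference in flu was only 0.28 and -0.09.

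**Figure D3:**
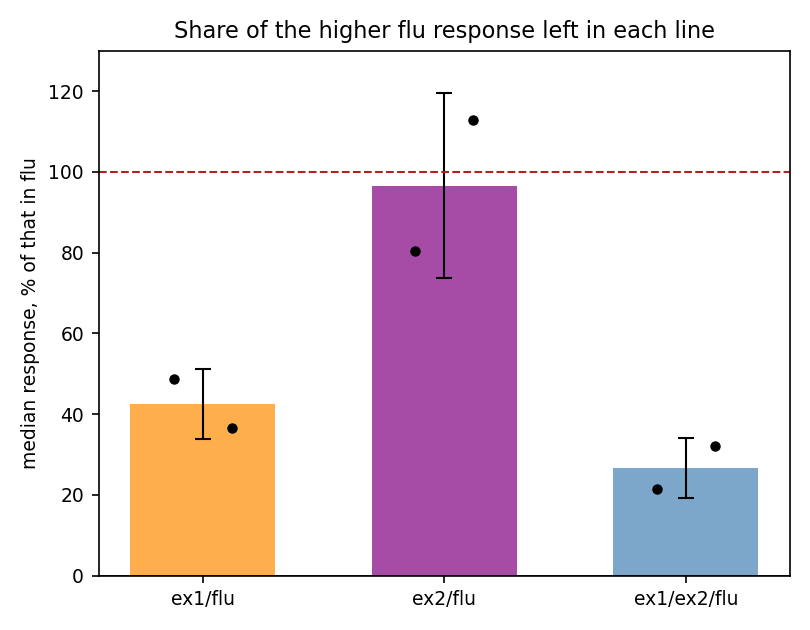
Share of the higher flu response left in each EXECUTER line, in percent of the median response in flu (dashed line), with 1 dot per selection, bars for the mean and error bars for the SD (n = 2 selections, which swap the same arrays). Means of 42.6% (ex1/flu), 96.5% (ex2/flu) and 26.8% (ex1/ex2/flu) were left.

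Of the 408 probe sets higher in flu, 134 were called lower than flu in ex1/flu, 22 in ex2/flu and 239 in ex1/ex2/flu, and 129 in both ex1/flu and ex1/ex2/flu. Independent calls would share 4.66, 2.88 and 10.3. Data simulated with no effect shared at most 1 in any of 20 simulations, but since almost nothing is called in such data, this does not show how much overlap the shared flu arrays bring among real calls. STZ, WRKY53, DLAH and AT3G10930 were among the 129. The mean of the line lay below that of flu for 392 of the 408 in ex1/flu, 178 in ex2/flu and 395 in ex1/ex2/flu. Against wild type 93 were still called higher in ex1/flu, 280 in ex2/flu and 36 in ex1/ex2/flu (independent expectation 2.94, 11.2 and 1.58), and 23 of the 36, STZ and AT5G66650 among them, were also lower in ex1/ex2/flu than in flu. Of the 147 lower in flu, 12 were higher than flu in ex1/flu, 19 in ex2/flu and 22 in ex1/ex2/flu. Among the 29 of them assigned to a locus within 4 Mb of FLU, these counts were 0, 7 and 3, so linked sequence may have a part in the count of ex2/flu. Because each pair of comparisons shares the flu or the wild type arrays, and 2 arrays cannot be split into groups of at least 2, part of the excess may come from the shared arrays, by an amount not measured here.

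The lines were also set against wild type. In ex1/ex2/flu, AT2G20870 rose by 2.40 ± 0.21 log2 units (n = 2 per genotype, limma adjusted p 1.42e-05), AT3G28500 by 2.04 ± 0.17, AT3G09540 by 1.90 ± 0.23, AT5G33370 by 0.97 ± 0.22 and AT4G29780 by 0.93 ± 0.18. The genes ranked lowest by the naming rule were AT3G22240 (-7.32 ± 0.33), AT3G19515 (by at least 3.08), AT1G68620 (-1.98 ± 0.28), CHI (-1.77 ± 0.22) and EX1 (-1.75 ± 0.17). Other named genes, such as LHCB4.2 (-1.07 ± 0.12), were also called lower. AT5G33370 was not called after quantile normalization, without the filter, without the trend or with a block for spike-in level, and AT4G29780 not without the trend. In all, 56 probe sets were higher and 124 lower, and no list was called by camera (lowest adjusted p over the 7 lists 0.104, and 0.486 with the estimated correlation). The total of 180 was 99 without the trend and 276 with only the arrays compared, and it was 62 without wild type 1, 88 without wild type 2 and 53 without ex1/ex2/flu 2.

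In ex1/flu against wild type, AT2G20870 (2.37 ± 0.21), AT1G05575 (2.12 ± 0.23), AT3G09540 (1.96 ± 0.23), AT3G28500 (1.79 ± 0.17) and AT1G72920 (1.74 ± 0.17) ranked highest by the naming rule, among genes of at least median signal. Other named genes, such as STZ (1.63 ± 0.15), were also called higher. AT3G22240 (-6.82 ± 0.33), AT3G19515 (by at least 3.11), AT1G68620 (-1.93 ± 0.28), CHI (-1.81 ± 0.22) and EX1 (-1.50 ± 0.17) fell. In ex2/flu against wild type, AT1G05575 rose by 4.26 ± 0.23 and AT3G10930 by 3.79 ± 0.21, and AT5G66650 by at least 4.01, AT2G22880 by at least 3.83 and AT1G14480 by at least 2.75, the last 3 from wild type signals below the level of the filter. AT3G22240 (-7.02 ± 0.33), AT3G19515 (by at least 3.13), CHI (-2.57 ± 0.22), AT1G76960 (-2.25 ± 0.27) and AT1G68620 (-2.14 ± 0.28) fell (n = 2 per genotype throughout). By limma, 104 probe sets were higher and 124 lower in ex1/flu, and 397 were higher and 291 lower in ex2/flu. The total of 228 for ex1/flu was 147 without the filter, 151 without the trend, 99 without wild type 1 and 97 without wild type 2, and more were higher than lower without either wild type array, without ex1/flu 1, without the filter, with median centring and at an adjusted p under 0.01. The total of 688 for ex2/flu was 444 and 423 without those arrays and 450 without ex2/flu 2.

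What the loss of EX2 adds once EX1 is lost was read from ex1/ex2/flu against ex1/flu. WRKY53 stood at 9.50 against 10.04 in mean log2 signal, STZ at 10.55 against 11.33 and DLAH at 6.67 against 7.32, and none of them was called. Of the 408 probe sets higher in flu, 311 had a lower mean in ex1/ex2/flu than in ex1/flu. Limma called 0 probe sets higher and 5 lower, none of the 5 assigned to 1 gene, and 786 had an unadjusted p under 0.05. The direction was not stable: 6 were higher and 1 lower without ex1/flu 2, 7 and 10 without ex1/flu 1, and 1 and 0 without ex1/ex2/flu 2. Without 1 array the count of 5 was 0 (flu 1 or flu 2), 1 (wild type 1, wild type 2 or ex1/ex2/flu 2) or 17 (ex1/flu 1), and it was 10 with median centring, 1 with only the arrays compared, and 0 without the filter, without the trend or with a block for spike-in level.

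Whether the effect of losing EX2 depends on EX1 was tested as an interaction, and the single lines were set against each other, a comparison added after the data were seen. The defence genes THI2.1 (AT1G72260, a thionin) and PDF1.2 (AT5G44420, a defensin) had interactions of -2.48 ± 0.36 and -2.05 ± 0.39 (log2, n = 2 per genotype, limma adjusted p 0.0114 and 0.0474), and XTH19 of -2.28 ± 0.24. Their mean log2 signals in flu, ex1/flu, ex2/flu and the line lacking both were 7.47, 8.23, 8.69 and 6.97 for THI2.1, 10.93, 11.07, 11.76 and 9.86 for PDF1.2, and 8.16, 8.65, 9.42 and 7.62 for XTH19. AT3G22240 (5.51 ± 0.46), CHI (1.93 ± 0.31) and AT5G57655 (1.67 ± 0.24) had positive interactions, with similar falls from flu in the single lines and in the line lacking both genes for AT3G22240. Its 2 single falls added up would have put ex1/ex2/flu at a log2 signal of 1.48, below the level of the filter (6.51), so any signal above that level gave a positive value, and the sign says nothing on how the effects combine. With AT3G22240, this held for 4 of the 10 positive interactions and for 0 of the negative ones. PDF1.2 was not called after quantile normalization, CHI, THI2.1 and PDF1.2 not without the filter, and of these 6 genes AT3G22240 and XTH19 were the ones still called without the intensity trend. LHCB4.2 (-0.95 ± 0.16) and AT3G10930 (-1.68) were also among the negative interactions. Both lie within 4 Mb of FLU, as does AT3G22240, so linked sequence that differs between the lines may have a part in their values. In all, 10 interactions were positive and 19 negative, and the total of 29 was 8 without the filter, 3 without the trend, 3 without flu 1, 91 without ex1/flu 1, 47 without ex1/flu 2, 10 without ex2/flu 1 and 7 without ex1/ex2/flu 1. The balance of signs rested on single arrays: it was 30 positive and 17 negative without ex1/flu 2, 14 and 8 without ex2/flu 2, 18 and 10 without ex1/ex2/flu 2, and 2 and 1 without flu 1 or without the trend.

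In ex1/flu against ex2/flu, AT3G10930 was lower by a log2 difference of -3.02 ± 0.21 (n = 2 per genotype, limma adjusted p 3.73e-06), AT2G22880 of -2.61 ± 0.49, XTH18 of -2.53 ± 0.28, AT4G39670 of -2.25 ± 0.23 and AT5G64870 of -2.18 ± 0.28. AT3G09540 (1.03 ± 0.23), AT2G15020 (0.96 ± 0.19), GIS (0.80 ± 0.19), CRR42 (0.79 ± 0.17) and DRT100 (AT3G12610, 0.74 ± 0.17) were higher. AT3G10930, AT3G09540 and DRT100 lie within 4 Mb of FLU, so linked sequence that differs between the lines may have a part in their values. All 5 of the higher genes lost their call with only the arrays compared, and AT2G22880 without the intensity trend. In all, 14 probe sets were higher and 264 lower in ex1/flu, and 185 were called without ex2/flu 2.

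The flu allele was brought from Landsberg erecta into Columbia by 5 backcrosses, so the calls were counted around FLU on chromosome 3. LHCB4.2, AT3G07950, AT3G11500, AT3G14220 and AT3G19515 are among 29 lower calls within 4 Mb of FLU, of 70 lower calls in flu with a locus, and 34 of the 70 lie on chromosome 3. Within 2 Mb, 20 of 378 probe sets (5.29%) were lower in flu against 50 of 7408 elsewhere (0.675%), an odds ratio of 8.22 (Fisher's exact test, two-sided, p 5.57e-11, adjusted p 6.69e-10 over 24 tests). The odds ratio for lower calls against wild type was 7.29 in ex1/flu (adjusted p 1.73e-06), 2.51 in ex2/flu (0.013) and 6.19 in ex1/ex2/flu (1.4e-05). AT3G10930, which rose in flu, and AT3G09540, AT3G18250, AT3G22240 and DRT100, named in other comparisons, also lie within 4 Mb of FLU. Higher calls in flu did not crowd there (odds ratio 1.39, p 0.241, adjusted p 0.385). Neighbouring probe sets are not independent of each other.

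**Figure D4:**
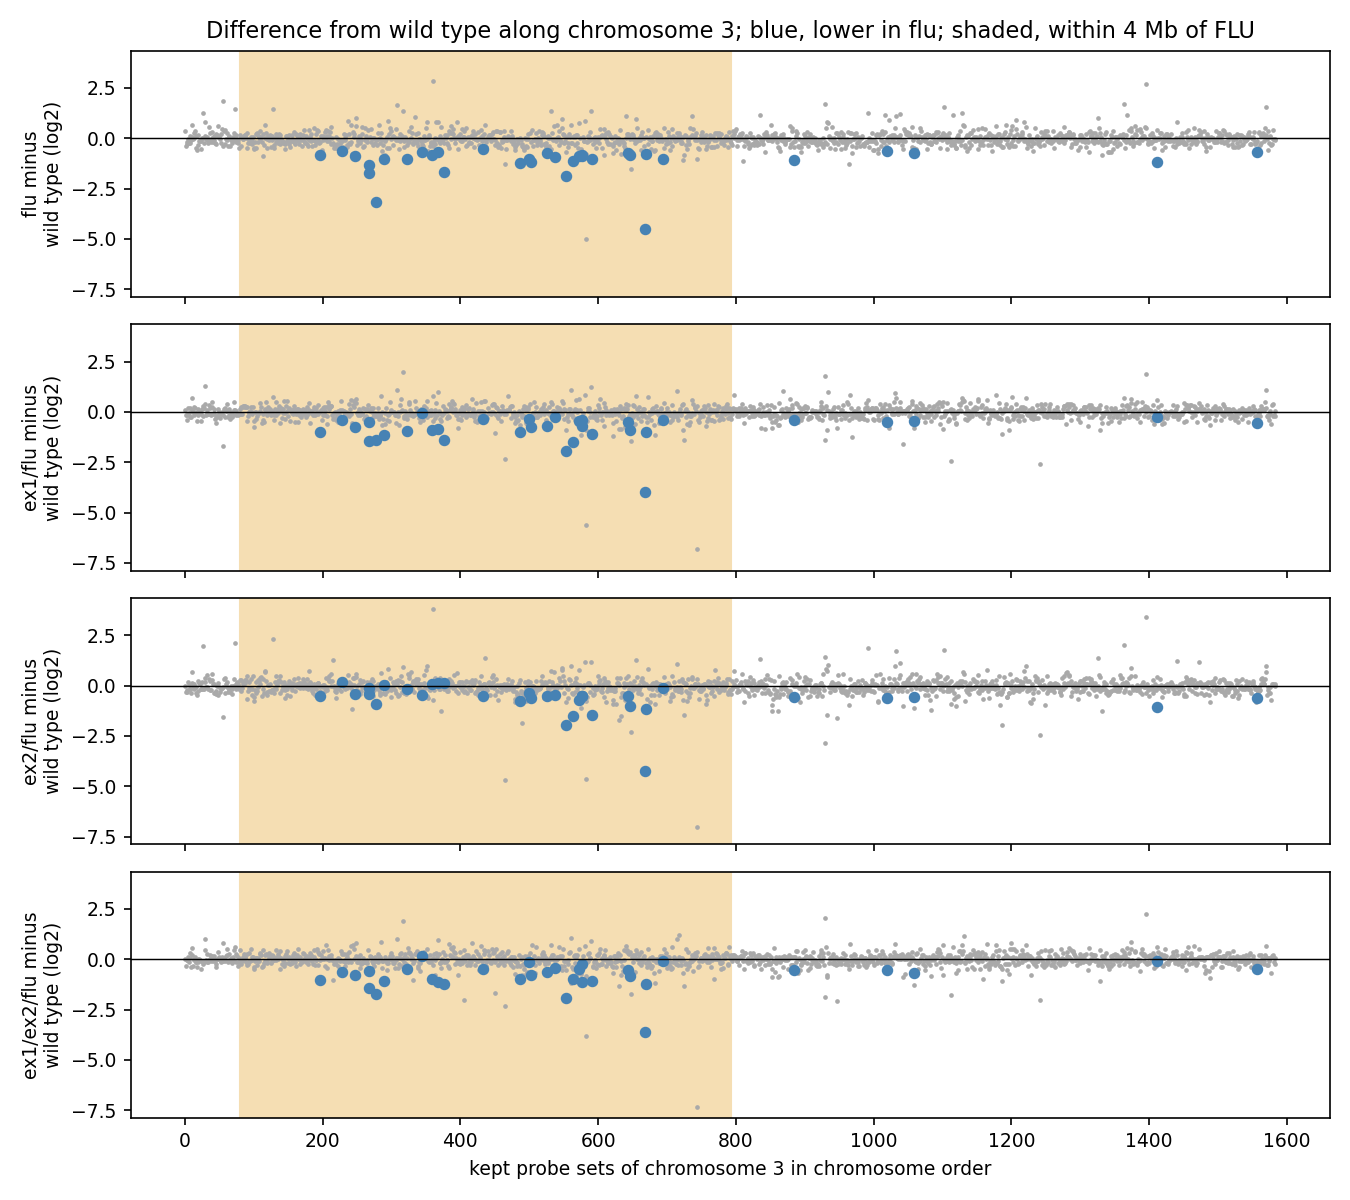
Log2 difference from wild type of the probe sets of chromosome 3 in chromosome order, with 1 panel per flu line, mean of 2 arrays per genotype. Large blue points mark the 34 probe sets lower in flu, of which 29 lie within 4 Mb of FLU (shaded).

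The poly-A spike-in controls split the arrays into a group of low level (wild type 1, flu 2, ex1/flu 2 and ex2/flu 2, geometric mean signal 102 to 118) and one of high level (the other 6, 156 to 231), a split the labels do not name. The cut was the midpoint of the range of the arrays' mean log2 spike-in signal. Nearest to it was ex2/flu 1 (7.29), between wild type 1 (6.89) and the next array of the high group, ex1/ex2/flu 2 (7.54). Within each group, over the 408 probe sets higher in flu, STZ, DLAH and WRKY53 among them, the median difference from flu was -0.67 (low) and -0.72 (high) in ex1/flu, 0.02 and 0.12 in ex2/flu, and -0.89 (high only) in ex1/ex2/flu. Both ex1/ex2/flu arrays were in the high group. With the level as a block, limma called 491 higher and 239 lower in flu, 72 and 242 in ex1/flu against flu, 115 and 188 in ex2/flu against flu, and 100 and 353 in ex1/ex2/flu against flu.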

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

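The explanations weighed in this part were tested only after the results were seen, and the comparison of ex1/flu with ex2/flu was itself added after the data were seen. The interaction of ex1 and ex2 asks whether losing EX2 has another effect once EX1 is lost. THI2.1 (-2.48), XTH19 (-2.28) and PDF1.2 (-2.05) had negative interactions on the log2 scale, and AT3G22240 (5.51), CHI (1.93) and AT5G57655 (1.67) positive ones. In all, 10 probe sets were higher and 19 lower by that test, and between ex1/flu and ex2/flu 14 were higher and 264 lower in ex1/flu. These results are listed because the test of the difference itself passed its threshold. Some of these calls lie within 4 Mb of FLU, where linked sequence may differ between the lines. For AT3G22240 the sign carries no information: the sum of the single falls would put ex1/ex2/flu at 1.48, below the level of the filter (6.51), and with it this held for 4 of the 10 positive interactions. Of the 6 genes, AT3G22240 and XTH19 were the ones still called without the intensity trend, and the 29 calls became 3 without flu 1 and 91 without ex1/flu 1. The excess of negative interactions turned with single arrays: there were 30 positive and 17 negative without ex1/flu 2, 14 and 8 without ex2/flu 2, and 18 and 10 without ex1/ex2/flu 2.

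The response of STZ, WRKY53 and DLAH to flu was reduced in ex1/flu and ex1/ex2/flu but not in ex2/flu. A difference between the groups of arrays with low and high spike-in level is argued against. Over the 408 probe sets higher in flu, the median of ex1/flu minus ex2/flu was -0.70 in the low group and -0.73 in the high group. Each group held 1 array per line. The spike-in signals of the 2 arrays were close in the low group (108 and 102) but not in the high group (231 and 156), where ex2/flu 1 lay near the cut. Exchanged labels of ex1/flu and ex2/flu are argued against by the EX1 probe set, lower in ex1/flu than in ex2/flu by a log2 difference of -1.30 ± 0.17. Array scaling is argued against too, since after quantile normalization ex1/flu kept 44.4% ± 9.42 (SD, n = 2 selections, which swap the same arrays) of the response and ex2/flu 97.9% ± 21.6. A greater part of EX1 than of EX2 in passing on the singlet oxygen signal is a candidate explanation, as a hypothesis read from the same data. No probe set was assigned to EX2, so the loss of its RNA in ex2/flu was not checked, and EX2 activity left there stays open. A difference between the inserted lines other than the lost gene stays open too, as untested, since this design holds no other insertion line of either gene.

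AT3G22240 was among the strongest signals in wild type (log2 14.37 and 14.24) and flu (14.05 and 12.56), and lay between 6.73 and 7.62 on all 6 arrays of the EXECUTER lines. Landsberg sequence fixed in the flu line is argued against by the flu level itself, -1.01 ± 0.33 from wild type. The spike-in level is argued against by differences of -4.93 to -6.68 from flu within each group. A deletion reaching the nearest 2 measured loci on each side is argued against by their values, none of them called and the lowest at -0.28 ± 0.20. A smaller deletion, of AT3G22240 alone or with unmeasured neighbours, was not tested. AT3G22240 itself lies within 4 Mb of FLU. Loss of either EXECUTER gene remains a candidate explanation, since ex1/flu and ex2/flu differed by only 0.20, but it cannot be told apart from a sequence that the EXECUTER lines share and flu lacks: this design holds no other insertion line.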

How the results depend on the processing

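The spike-in block and the omission of probe sets near FLU were chosen after seeing the data, as was the comparison of ex1/flu with ex2/flu. Over the alternatives other than leaving out an array, no called gene changed direction. Of the 121 values of named genes, all kept their side of the threshold with median centring and with the offset, 119 with quantile normalization, 120 with the spike-in block, 120 with the replicate block, 116 with only the arrays compared, 106 without the filter, 97 at an adjusted p under 0.01 and 93 without the intensity trend. The odds ratios of lower calls around FLU stayed above 1 with p under 0.05 in every alternative run for them.

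At an adjusted p under 0.01 the number called was 296 in flu against wild type, 96 (ex1/flu), 26 (ex2/flu) and 211 (ex1/ex2/flu) against flu, 109, 414 and 79 against wild type, 0 in ex1/ex2/flu against ex1/flu, 3 for the interaction and 181 in ex1/flu against ex2/flu, by the construction of the threshold. Without the intensity trend it was 106, 10 and 277 in the lines against flu, 151 (ex1/flu) and 99 (ex1/ex2/flu) against wild type, 0 in ex1/ex2/flu against ex1/flu and 3 for the interaction. The cause was not tested. With only the arrays compared it was 274 (ex2/flu) and 664 (ex1/ex2/flu) against flu, 276 in ex1/ex2/flu against wild type and 1 in ex1/ex2/flu against ex1/flu. Without the filter it was 42 in ex2/flu against flu, 147 in ex1/flu against wild type, 0 in ex1/ex2/flu against ex1/flu and 8 for the interaction, with more and dimmer probe sets tested. Median centring gave 10 in ex1/ex2/flu against ex1/flu, and 10 positive and 32 negative interactions. The replicate block together with quantile normalization gave 8 in ex1/ex2/flu against ex1/flu. The spike-in block gave 314 (ex1/flu) and 303 (ex2/flu) against flu, 0 in ex1/ex2/flu against ex1/flu and 57 for the interaction. The cause was not tested.

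Leaving out an array gave 256 to 716 calls in flu against wild type, 58 to 243 in ex1/flu, 8 to 258 in ex2/flu and 129 to 655 in ex1/ex2/flu against flu, 97 to 245 in ex1/flu, 423 to 881 in ex2/flu and 53 to 257 in ex1/ex2/flu against wild type. It gave 0 to 17 in ex1/ex2/flu against ex1/flu, 3 to 91 for the interaction and 185 to 277 in ex1/flu against ex2/flu. Where a genotype was left with 1 array, this array was assumed to vary like the others. Of the genes not called in flu against wild type, 6 changed sign: GR (-0.12 to 0.50), CHIL (-0.55 to 1.09), AT3G09630 (-0.0229 to 0.175), EX1 (-0.00074 to 0.35), SAG101 (-0.52 to 0.11) and GSTU25 (-1.17 to 0.0173, below the level of the filter in both genotypes).

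Without the filter, the share of the response higher in flu was 72.3% in ex1/flu, -11.2% in ex2/flu and 121% in ex1/ex2/flu, and that of the lower response -75.6%, 164% and -57.5%. For the higher response the selections then had median flu differences of 0.28 and -0.09, so the ratio had little to divide by. For the lower response they were -0.0661 and -0.535, against -0.363 and -0.594 in the main setting, so this held for 1 of the 2 selections, and the cause in the other was not tested. The lower response left was 111% in ex2/flu with a 4-fold selection and 55.1% in ex1/flu without probe sets near FLU, and the cause was not tested. Of 35 list tests 10 were called, 9 to 12 in the alternatives, but 0 with the estimated correlation. Signal over background could not be judged, since the table held no detection calls. The 40th percentile of an array, the level of the filter, was 85.5 to 92.6.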

Other observations

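Apart from the planned count of calls within 2 Mb of FLU and the family groups, which were added before any difference was seen, the tests of this part were chosen only after the results were seen. The groups, mostly families defined by symbol, numbered 34 in each comparison. In flu, the U-box ubiquitin ligases PUB23 (1.22 ± 0.23, log2, n = 2 per genotype) and PUB24 (0.83 ± 0.17), the calmodulin-like CML23 (0.89 ± 0.19) and the glycosyltransferase UGT73B1 (1.66 ± 0.22) rose. UGT73B1 fell by 1.91 ± 0.22 and PUB24 by 1.00 ± 0.17 in ex1/flu against flu. In ex2/flu against flu, 2 of 5 XTH genes were higher (camera adjusted p 0.00389, and 0.234 with the estimated correlation), and CYP71B23 fell by 1.12 ± 0.24. In ex1/ex2/flu against wild type, 57 of 69 plastid-encoded probe sets lay above 0 with a median of 0.21, 2 of them called (camera adjusted p 1.5e-07, and 0.933 with the estimated correlation). No family call held with the estimated correlation.

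Some probe sets were called in all lines. Higher than wild type in all 4 flu lines were 30 probe sets, 13 with 1 gene, among them STZ, AT5G66650, AT4G29780, AT1G72920, AT1G72940 and IAGLU. Of these 13, 4 were not lower in ex1/ex2/flu than in flu: AT2G20870 (1.82 ± 0.21 in flu and 2.40 ± 0.21 in ex1/ex2/flu against wild type), AT3G28500 (1.70 ± 0.17 and 2.04 ± 0.17), AT3G09540 (1.35 ± 0.23 and 1.90 ± 0.23) and RXF26. AT3G09540 lies within 4 Mb of FLU, so linked sequence may account for it, and RXF26 was below the level of the filter in wild type and flu, so its differences are not given. Lower than wild type in all 4 were 26 probe sets, 9 with 1 gene, and 7 of these, such as AT3G19515 and NAI2, lie within 4 Mb of FLU. Lower than flu in all 3 EXECUTER lines were 10 probe sets, 7 with 1 gene: AT3G22240, CHI, AT1G68620, AT2G30600, AT5G57655, AT1G49050 and GAMMA-VPE. Higher than flu in all 3 were 5, with rpl20 and AT1G17090 the ones assigned to 1 gene. Independent calls would give 0.000314, 0.000219, 0.0293 and 0.000516 for these 4 counts, and 20 simulations with no effect gave 0 in each. Neither value holds both real effects and the shared wild type or flu arrays, so part of the agreement may come from those arrays.

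Lower calls in flu crowded around FLU. Repression that needs EX1 or EX2 is argued against as the whole cause, since 22 of 29 lower calls within 4 Mb had at least 50% of the flu difference left in ex1/ex2/flu, against 12 of 41 elsewhere (Fisher's exact test, two-sided, p 0.000214), though 3 were called higher than flu there and 7 in ex2/flu. The odds ratio after quantile normalization was 8.65. Both scaling and this normalization act on whole arrays without regard to position, so no conclusion on array scaling is drawn from it. Landsberg sequence linked to FLU is a candidate explanation: within 4 Mb a median of 81.8% of the flu difference was left in ex1/ex2/flu, against 37.8% for the 41 lower calls elsewhere (permutation test, two-sided, p 0.00127). All shares left around FLU and elsewhere were taken on the same flu and wild type arrays that made the calls. Random deviations of those arrays therefore enter these shares. A hypothesis read from the same data is that ex2/flu carries a shorter linked segment: 13 of the 29, AT3G07950, AT3G11500 and LHCB4.2 among them, had under 50% of the difference left in ex2/flu, 10 of them in the lower 14 positions of chromosome order and 3 in the upper 15 (permutation p 0.00354). The same 13 kept a median of 72.0% in ex1/ex2/flu and 82.9% in ex1/flu. Of the 13, SCPL27 (42.0%), AT3G09700 (49.3%), AT3G14740 (15.3%), AT3G15570 (45.0%) and AT3G20240 (8.65%) had under 50% left in ex1/ex2/flu as well. The rest of the 13 had over 50% left there. SCPL49, which lies between AT3G09700 and AT3G10860, kept 70.2% in ex2/flu, so the stretch was not unbroken. Probe mismatch and changed expression of linked genes could both give these values, and neighbouring genes are not independent, so the p is a description; sequence around FLU was not read here.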
